A study of Mus musculus with 9 samples.

How the data were processed

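Gene expression was measured by RNA sequencing in 9 libraries of mouse anterior lens capsule, the basement membrane at the front of the lens with the epithelial sheet that lies on it. The labels put 3 libraries in each of 3 groups, which are young control mice, aged control mice and aged mice given epigallocatechin gallate (EGCG), a catechin of green tea. The ages, the dose, the route and the duration of treatment are not given in the sources used here. Nothing in the labels says whether the 3 libraries of a group came from separate animals, from pools or from repeats of 1 preparation, so p-values measure only the spread between these samples, which may be technical.

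Per the labels' protocols, total RNA was made into libraries with a SMARTER mRNA-Seq kit. Per the submitters' processing notes, the genome build was GRCm38 (mm10). The aligner, the counting tool, its annotation and its use of strand are not given in the sources used here. The authors deposited a table of whole-number read counts per gene symbol, with no normalization, and a second table of FPKM values, which are fragments scaled to gene length and library total. In all 138164 entries with a count, the deposited FPKM value equalled the deposited count divided by 1 length per gene and by the library total, within 0.01%, and the 19579 entries with a count of 0 had an FPKM of 0. For the 779 genes with a count in only 1 library this holds by construction, since the length is taken from the same relation. The FPKM table therefore carries no scaling beyond library size. Gene lengths used below are the lengths implied by that relation. Each table holds 17527 gene symbols, of which 17316 had at least 1 count, and no entry of the tables lacks a gene name. No mitochondrially encoded gene is among the symbols.

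Library totals ranged from 13184169 to 16528179 counts. A count of 3 in a library corresponds to between 0.182 and 0.228 CPM (counts scaled to a common library total), and intervals cover counting error and the spread between libraries only. The 10 most abundant genes took between 25.4% and 34.5% of the counts of a library. Libraries of 1 group correlated with r between 0.9931 and 0.9949 across genes on log2(CPM + 1), where genes are not independent replicates. The median chi-square of a pair of libraries over sampling noise lay between 2.61 and 4.75, above the value of 1 that sampling alone gives, so no pair was treated as 1 library deposited more than once.

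The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, run on the deposited counts with TMM scaling factors, after filterByExpr had left 13711 genes. All 9 libraries entered 1 fit of group means, so the 3 groups shared 1 estimate of the spread, and the biological coefficient of variation was 7.9%. TMM factors were 0.881 to 0.926 in the aged control, 0.981 to 0.989 in the EGCG and 1.119 to 1.131 in the young control libraries. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called changed at an adjusted p under 0.05. Levels are given as TMM-scaled CPM with the SD over the 3 libraries of a group. The standard error of a log2 fold change was taken from the size of the change and its F statistic. The 3 comparisons were aged control against young control, aged EGCG against aged control, and aged EGCG against young control.

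Before the data were examined, 36 gene lists with 999 genes were fixed for lens cells, the pathway in the series title, stress and signalling pathways, and other cell types of the eye. Of their genes, 947 are in the tables. The lists of mitochondrially encoded genes and of core histone genes have no gene there, and the list of lymphocyte and neutrophil markers had 1 tested gene, which was not called in any comparison, so 33 lists were tested. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with a correlation estimated from the data and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were run beside it. Which lists are described in detail was chosen after their values were seen. Where no second count is given, the counts of changed members adjusted over the list alone equalled those over all genes.

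Genes are named by a rule fixed before the data were examined. It takes Rassf2 and genes of the AKT kinases. It then takes the 8 higher and 8 lower genes with the smallest p in each of the first 2 comparisons and the 3 higher and 3 lower ones in the last, among genes with an adjusted p under 0.05, a change of at least 2-fold, at least 5 CPM in the higher group, no overlap between the groups and a symbol other than a predicted-gene or RIKEN name. From each list described it takes up to 4 called members with the smallest p. Members named outside this rule, to spell out a count of 5 or fewer or to illustrate a statement, were chosen after their values were seen and are marked as such. Some genes that the rule picks are not reported here and were not replaced. Coordinates come from the GENCODE M21 annotation of GRCm38, in which 16897 symbols matched 1 gene each, 98.4% of them protein coding.

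The alternatives fixed beforehand were other scaling factors (RLE, upper quartile, library size only), DESeq2 1.42.0, limma-voom, no or a stricter filter on low counts, a fit of only the groups compared, a robust fit, a threshold with a 2-fold change, leaving out crystallin, haemoglobin and mitochondrial genes, the replicate number as a block, the FPKM values in limma on log2(FPKM + 1) and log2(FPKM + 0.1), and leaving out each library in turn. Chosen after seeing the data were a fit without the 1005 genes at least 2-fold lower in aged than young control and at least 2-fold higher in EGCG than aged control, called here retina-following genes although they were picked by these changes alone and include the 4 haemoglobin genes, a scaling to the lens fibre gene list, and the removal of each library's trend over gene length. To judge the comparisons that share the aged control libraries, 20 sets of unchanged libraries were simulated.

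The tests were checked on simulated counts with known changes, drawn from the means and library sizes of the deposited data. Few genes were changed, in random directions. For aged against young control 66 were changed at each fold size, where 69.2% of genes were called in the deposited data. The shares of false calls below therefore do not cover errors of scaling when many genes change. For aged against young control, with 13535 genes tested, edgeR recovered 59.1% of genes changed 1.5-fold, 86.4% of those changed 2-fold and 97% of those changed 4-fold, and 4.2% of its calls were false. For aged EGCG against aged control, with 13530 genes, the recovered shares were 60.6%, 83.6% and 95.4%, with 5.4% false calls. For aged EGCG against young control, with 13500 genes, they were 61.5%, 76.6% and 100%, with 4.9% false calls. With the ribosomal protein list moved as well, camera at its preset correlation called that list in each comparison. Of the other lists it called 1, 1 and 0, and these may hold some of the changed genes. The simulated genes were independent, so the preset correlation itself was not checked. On counts given an artificial length trend for aged against young control, removing the trend lowered the false calls from 4796 to 5 and recovered 158 of 198 changed genes. That trend was stronger than the real one (Spearman correlation −0.83 against −0.33), and the changed genes were drawn at random. The check therefore does not cover changed genes of similar length, such as the ribosomal protein genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.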

Results

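The transcriptome of the mouse anterior lens capsule was measured in 3 young control, 3 aged control and 3 aged EGCG-treated libraries, with 13184169 to 16528179 counts per library. The series title names the delay of age-related cataract by EGCG and the RASSF2/AKT pathway. The comparisons ask which transcripts differed with age, which differed with EGCG in aged tissue, and how EGCG-treated aged tissue differed from young tissue. Crystallins, the structural proteins of the lens, were among the most abundant transcripts, and Cryaa alone took between 7.95% and 11.71% of the counts of a library. Markers of the retina were also present. Without Dkk3, which is also on the lens epithelium list, the 33 others tested took 2.79% of the CPM in young control, 0.19% in aged control and 1.28% in EGCG libraries, with a coefficient of variation within each group of 0.4%, 2.0% and 1.0%. Dkk3 alone had 1805, 3015 and 2898 CPM, and with it the shares were 2.97%, 0.50% and 1.57%.

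In aged against young control capsule, the γ-crystallin transcripts Crygb, Crygc and Crygd fell, 33 of 34 retinal markers fell, and 20 of 26 genes of the senescence and p53 target list rose while 3 fell. Ribosomal protein genes were also higher, a camera call lost with an estimated correlation (adjusted p = 0.185). Cdkn1a, the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727, plus strand, protein coding), rose from 1.58 ± 0.255 to 85.4 ± 6.77 CPM (SD, n = 3 each), a log2 fold change of 5.75 (SE 0.121, edgeR adjusted p = 1.36e-37). Ccng1, cyclin G1, another p53 target (chromosome 11, 40748552 to 40755311, minus strand), rose 7.47-fold from 278 ± 1.88 to 2075 ± 35.7 CPM. Crygb, a γ-crystallin of lens fibre cells (chromosome 1, 65080219 to 65082288, minus strand), fell 99.9-fold from 13450 ± 163 to 135 ± 3.45 CPM (log2 fold change −6.64, SE 0.0546, adjusted p = 5.47e-54). Gnat1, the transducin of rod photoreceptors (chromosome 9, 107674474 to 107679712, minus strand), fell 18.1-fold from 3553 ± 23.5 to 197 ± 11.7 CPM (log2 fold change −4.17, SE 0.0469, adjusted p = 1.29e-48).

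Of 13711 genes tested, 9482 were called changed between aged and young control, 4847 higher and 4635 lower. At a change of at least 2-fold, 1017 were higher and 2625 lower. In 72.1% of the genes tested the 3 libraries of one group all lay above the 3 of the other, where chance gives 10%. The rule also picked as higher Aldh3a1 (5.02-fold), an aldehyde dehydrogenase that is abundant in the cornea, Ephx1 (5.99-fold), the microsomal epoxide hydrolase, Pea15a (3.03-fold), Rpl4 (3.08-fold), Phlda3 (9.04-fold) and Serpinb6b (5.33-fold). Among the lower genes were Crygd (69-fold), Crygc (47.9-fold), and the photoreceptor genes Prph2 (17.3-fold), Pdc (27.4-fold) and Rbp3 (16.3-fold). The split depended on scaling. With library size only it was 2937 higher and 6445 lower, on log2(FPKM + 1) it was 2926 and 5575, and scaled to the lens fibre genes it was 2022 and 7475, where the median of all genes moved by −0.322, −0.296 and −0.483 on the log2 scale.

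The senescence and p53 target list rose with age, with 20 of 26 tested members higher, 3 lower and 3 not called, and a median log2 fold change of 0.84 (camera adjusted p = 4.61e-08, and 0.0176 with an estimated correlation). The list had 15 higher, 6 lower and a median of 0.52 with library size only, and 14, 8 and 0.36 scaled to lens fibre genes. Besides Cdkn1a and Ccng1, Phlda3 rose from 12.5 ± 0.808 to 113 ± 10.5 CPM, and Cdkn2b, the cyclin-dependent kinase inhibitor p15, rose 13.8-fold from 3.57 ± 0.417 to 49.2 ± 2.06 CPM. The 3 lower members, named after their values were seen, were Lmnb1 (2.80-fold), the nuclear lamina protein lamin B1, Plk2 (3.50-fold) and Sirt1 (1.89-fold). The antioxidant and NRF2 target list had 32 of 38 members higher, none lower and a median of 0.82 (camera adjusted p = 2e-08, but adjusted p = 0.066 with an estimated correlation), but 26 higher, 6 lower and 0.49 with library size only, and 20, 9 and 0.33 scaled to lens fibre genes. Its members with the smallest p were Gss (2.90-fold), glutathione synthetase, Ftl1 (2.40-fold), the ferritin light chain, Gpx3 (3.12-fold), the extracellular glutathione peroxidase, and Gstm1 (2.28-fold), a glutathione S-transferase.

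The crystallin list moved in both directions with age. Of its 16 members 8 were higher and 8 lower, but 4 higher and 10 lower both scaled to lens fibre genes and with the length trend removed. The median log2 fold change was 0.04, which turned to −0.44 in those settings and −0.28 with library size only, whereas the mean was −2.67 and camera called the list lower (adjusted p = 5.85e-12, and 0.0472 with an estimated correlation). Crygd fell from 9025 ± 250 to 131 ± 11.7 CPM and Crygc from 8625 ± 93.3 to 180 ± 18.8 CPM, and together with Crygb they lie within chromosome 1, 65061872 to 65082288. Crygf fell from 153.5 ± 0.728 to 0.259 ± 0.0746 CPM, so its aged level is close to the floor of counting. The γ-crystallin genes are related copies that differ in sequence, and how any reads that match several of them were counted is not known. Of 21 other lens fibre genes 15 were higher and 5 lower, with a median of 0.44 (camera adjusted p = 0.00707, but adjusted p = 0.0962 with an estimated correlation); when these genes themselves set the scale the median was −0.04, and with library size only it was 0.12, with 11 higher and 6 lower. Cd24a (2.16-fold), Gja3 (2.23-fold), a gap junction protein of fibre cells, and Cdkn1c (2.22-fold) rose, and Dnase2b, the nuclease that removes nuclear DNA from fibre cells, fell 3.30-fold. The other 4 lower members, named after their values were seen, were Birc7 (2.15-fold), Lenep (1.29-fold), Lgsn (1.16-fold) and Bfsp1 (1.07-fold). Among lens epithelium genes 16 of 25 were higher and 6 lower, with a median of 0.60 (camera adjusted p = 0.0106, but adjusted p = 0.185 with an estimated correlation). Their split was 13 higher and 8 lower with a median of 0.28 with library size only, and 12 and 10 with 0.12 scaled to lens fibre genes. Aqp5, a water channel, rose 3.66-fold, Sfrp1 1.83-fold and Dkk3 1.67-fold, while Slc16a1, a monocarboxylate transporter, fell 5.04-fold.

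Cytosolic ribosomal protein genes rose with age in 75 of 76 cases, the exception (named after its values were seen) being Rpl34 with a log2 fold change of 0.11 and adjusted p of 0.112. Their median was 0.96, a 1.94-fold change (camera adjusted p = 1.44e-33, but adjusted p = 0.185 with an estimated correlation). Rpl4 rose from 1069 ± 8.96 to 3296 ± 170 CPM, Rps19 2.99-fold and Rpsa 2.48-fold. Ribosomal protein genes have many processed pseudogenes, with which reads could be shared. Across all genes, the change with age went with gene length, with a Spearman correlation of −0.33, and the median was 0.52 in the shortest 10% of genes and −0.57 in the longest 10%. Genes are not independent replicates, and the ribosomal protein genes are short. With each library's length trend removed, the ribosomal median was 0.50 and 64 genes were called higher, and scaled to lens fibre genes these were 0.48 and 65.

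Retinal markers fell with age in 33 of 34 cases, with a median log2 fold change of −4.14, a 17.6-fold decrease (camera adjusted p = 1.51e-139, and 6.96e-05 with an estimated correlation). Prph2, a structural protein of photoreceptor discs, fell from 1597 ± 15.8 to 92.5 ± 2.71 CPM, and Pdc, phosducin, from 687 ± 16 to 25 ± 0.336 CPM. The exception, Dkk3, is also on the lens epithelium list. Red blood cell markers fell in 5 of 7 cases (5 lower and 1 higher, Bpgm, named after its values were seen, when adjusted over the list alone), with a median of −4.62 (camera adjusted p = 8.92e-05, and 0.0472 with an estimated correlation). Hbb-bs fell 39.1-fold to 2.64 ± 0.744 CPM and Hba-a1 from 72.1 ± 3.99 to 2.91 ± 0.79 CPM, with Hba-a2 and Hbb-bt also lower, and the haemoglobin copies are near-identical. Alas2, a haem synthesis enzyme of red cells, named after its values were seen, was the remaining lower member. Endothelial and mural cell markers had 11 of 19 members lower and 1 higher, with a median of −1.11, which camera did not call (adjusted p = 0.237) and which was −0.48 on log2(FPKM + 1). Kdr (6.73-fold) and Flt1 (2.54-fold), receptors for vascular endothelial growth factor, and Rgs5 (4.50-fold), a pericyte marker, fell, and Pdgfrb rose 1.82-fold.

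**Figure D1:**
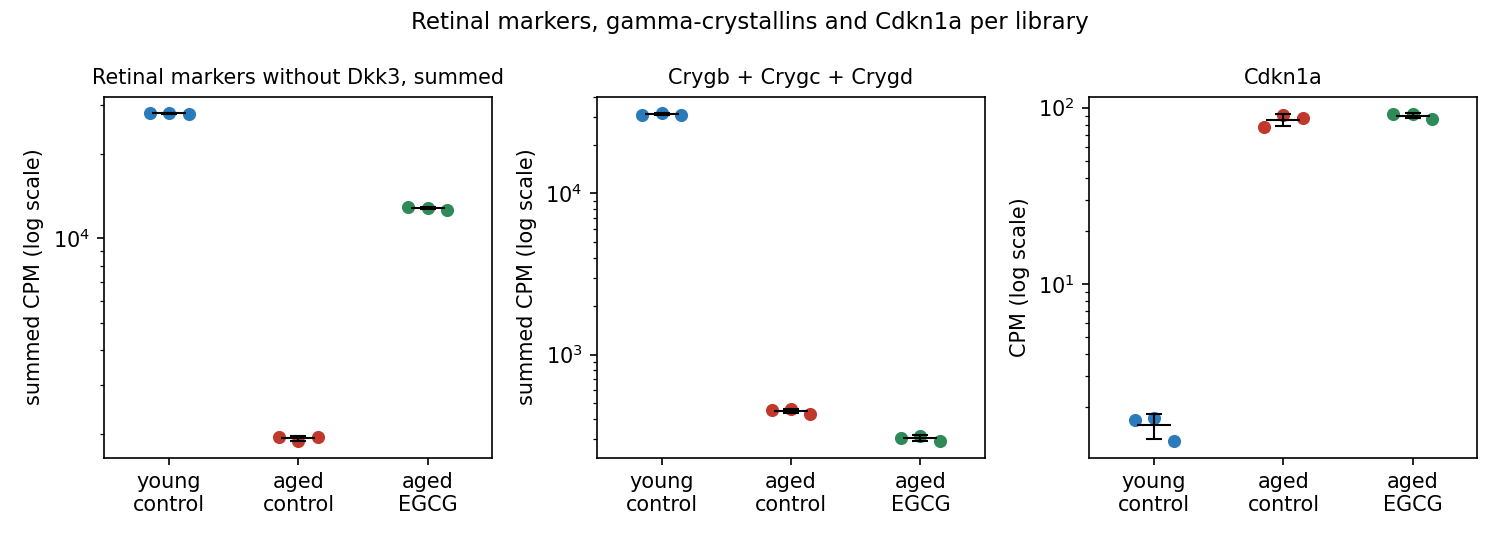
Summed CPM of the 33 retinal markers other than Dkk3, summed CPM of Crygb, Crygc and Crygd, and CPM of Cdkn1a in each library, on log scales, where points are libraries and bars the mean ± SD of 3 libraries per group. The retinal sum is 2.79% of CPM in young control, 0.19% in aged control and 1.28% in EGCG libraries, the γ-crystallin sum lies between 30792 and 31640 in young control, 428.6 and 457 in aged control and 289.5 and 313.8 in EGCG libraries, and mean Cdkn1a is 1.58, 85.4 and 90 CPM.

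The inflammatory and immediate early lists had members changed in both directions with age and no camera call. Inflammatory signalling genes were higher in 15 of 25 cases and lower in 3, with a median of 0.60 (camera adjusted p = 0.305), but 10 higher, 4 lower and 0.28 with library size only and 7, 4 and 0.12 scaled to lens fibre genes. Serpina3n, an acute-phase protease inhibitor, rose 3.98-fold, Tlr2, a pattern recognition receptor, 4.52-fold, and Rela, a subunit of NF-κB, 1.78-fold. Tnfaip3, an inhibitor of NF-κB signalling, fell 7.45-fold, and the other lower members, named after their values were seen, were Cxcl12 (2.86-fold) and Socs3 (2.03-fold). Immediate early genes were lower in 12 of 24 cases and higher in 5, with a median of −0.43 (camera adjusted p = 0.181). With library size only 18 were lower and 3 higher with a median of −0.75, and scaled to lens fibre genes the same counts had a median of −0.92. Fos fell 3.94-fold, Fosb 8.63-fold, Egr1 3.51-fold and Jun 2.56-fold. The 5 higher members, named after their values were seen, were Maff (7.09-fold), Fosl2 (2.23-fold), Klf6 (1.64-fold), Jund (1.30-fold) and Btg2 (1.13-fold).

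Rassf2, a Ras association domain protein that binds K-Ras and the MST kinases (chromosome 2, 131989415 to 132030258, minus strand, protein coding), rose with age and was lower with EGCG. Its level was 1.86 ± 0.139 CPM in young control, 4.86 ± 1.35 in aged control and 1.63 ± 0.37 in EGCG libraries (SD, n = 3 each), from 19 to 92 counts per library. The log2 fold change with age was 1.38 (SE 0.333, 95% interval 0.709 to 2.051, edgeR adjusted p = 0.000309), and that of EGCG against aged control −1.58 (SE 0.344, 95% interval −2.271 to −0.883, adjusted p = 0.000371). In both comparisons the 3 libraries of one group all lay above the 3 of the other. EGCG and young control libraries differed by −0.20 (95% interval −0.934 to 0.540, adjusted p = 0.653), a difference not detectable at this depth. On log2(FPKM + 1), which compresses low levels, the changes were 0.379 and −0.480.

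Akt1 (chromosome 12, 112653821 to 112674884, minus strand) and Akt2 (chromosome 7, 27591552 to 27640826, plus strand), kinases downstream of phosphoinositide 3-kinase, rose with age and were not called under EGCG. Akt1 rose from 89.6 ± 4.37 to 128 ± 4.22 CPM (log2 fold change 0.52, SE 0.059, adjusted p = 1.34e-10) and Akt2 from 41.8 ± 2.47 to 66 ± 0.927 CPM (0.66, SE 0.0749, adjusted p = 1.08e-10). For EGCG against aged control Akt1 differed by 0.07 (95% interval −0.045 to 0.189, adjusted p = 0.416) and Akt2 by −0.00 (95% interval −0.151 to 0.144, adjusted p = 0.982). Scaled to lens fibre genes the Akt1 change with age was 0.034 and not called (adjusted p = 0.65), while its change with EGCG was 0.248 and called (adjusted p = 0.00183), as it also was with library size only (0.200) and on log2(FPKM + 1) (0.194).

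The list of 36 genes of the RASSF2 and AKT pathway was not called by camera with age or with EGCG, while fry called it with age (adjusted p = 0.0385) and not with EGCG (adjusted p = 0.366). With age 15 were higher and 12 lower, with a median of 0.07 that turned negative with library size only (−0.25) and on the lens fibre scale (−0.41) but was 0.30, with 24 higher and 4 lower, with the length trend removed, and camera made no call (adjusted p = 0.646). Phlpp2, a phosphatase of AKT, fell 5.74-fold, Rictor, a part of mTOR complex 2, 2.31-fold, and Gsk3b, an AKT substrate, 1.74-fold, while Irs1, an insulin receptor adaptor, rose 1.94-fold. With EGCG 1 was higher and 6 lower, with a median of −0.01 (camera adjusted p = 0.372), a split that was 7 higher and 3 lower with library size only and 12 and 1 scaled to lens fibre genes. Besides Rassf2, the called members with the smallest p were Mtor (1.24-fold lower), Igf1r (1.27-fold lower) and Phlpp2 (1.41-fold higher). The Mtor and Igf1r calls were lost on log2(FPKM + 1) (adjusted p = 0.117 and 0.119) and scaled to lens fibre genes (0.109 and 0.0696). All these values are transcript levels, and the activity of the AKT pathway was not measured.

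**Figure D2:**
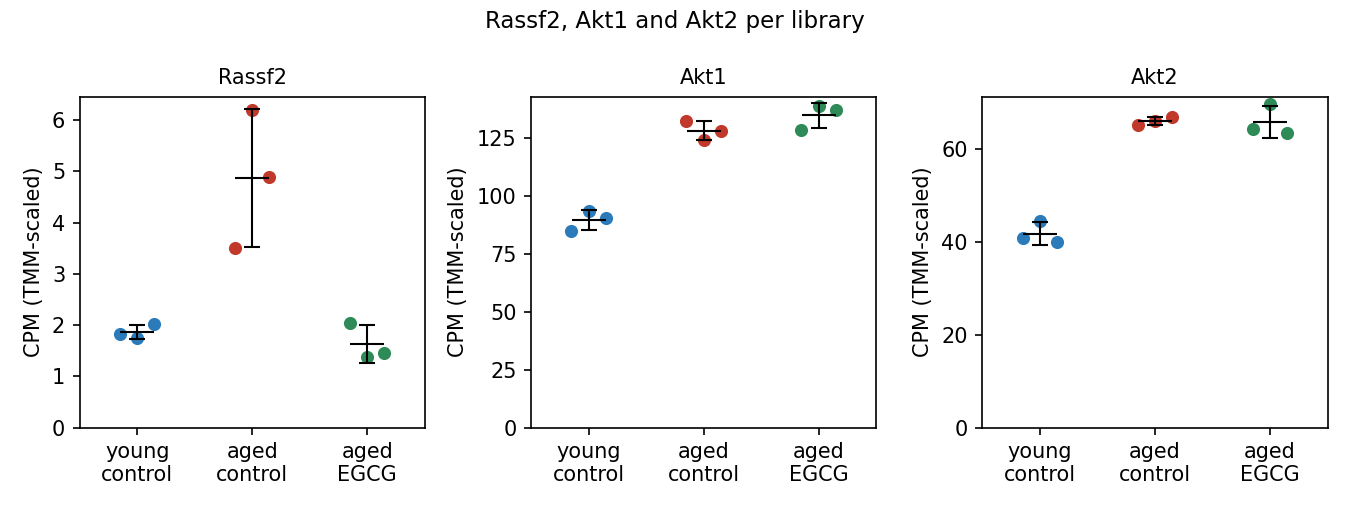
TMM-scaled CPM of Rassf2, Akt1 and Akt2 in each of the 9 libraries, with points for libraries and bars for the mean ± SD of 3 libraries per group. Mean Rassf2 is 1.86 in young control, 4.86 in aged control and 1.63 in EGCG libraries, and the 3 aged control libraries lie above the other 6.

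In aged EGCG against aged control capsule, 31 of 34 retinal markers rose. Camera called the capsule, fibrosis and inflammation lists lower with the preset correlation and not with an estimated correlation (adjusted p = 0.0702 for each), and fry called all 3. Gnat1 rose 9.84-fold from 197 ± 11.7 to 1936 ± 40 CPM (log2 fold change 3.30, SE 0.0454, edgeR adjusted p = 3.06e-44). Slc5a3, the sodium/myo-inositol cotransporter (chromosome 16, 92058322 to 92087473, plus strand), fell 2.40-fold from 94.8 ± 10.6 to 39.6 ± 2.67 CPM (log2 fold change −1.26, SE 0.0812, adjusted p = 1.05e-17), next to 37.3 ± 1.86 in young control. Ccn2, connective tissue growth factor (chromosome 10, 24595442 to 24598683, plus strand), fell 2.02-fold from 142 ± 8.37 to 70.4 ± 5.71 CPM (log2 fold change −1.01, SE 0.0657, adjusted p = 1.28e-17). Cdkn1a and Ccng1 did not pass the test, at 0.08 (95% interval −0.069 to 0.224) and 0.04 (95% interval −0.039 to 0.120).

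Between EGCG and aged control libraries 3300 genes were called changed, 1894 higher and 1406 lower. Of 1130 that changed at least 2-fold, 1016 (89.9%) were higher and 114 lower, and 1011 of the 1016 were lower in aged than in young control. In 33.5% of the genes tested the libraries did not overlap, where chance gives 10%. The rule also picked as higher the photoreceptor genes Prph2 (7.47-fold), Pdc (10.7-fold), Pde6g (14-fold), Guca1b (10.3-fold), Pde6b (9.29-fold) and Nrl (10.3-fold). The other lower genes were Vegfa (2-fold), Krt19 (2.39-fold), an epithelial keratin, Tnfrsf21 (2.29-fold), Hspa1b (2.20-fold), a heat shock protein whose reads can be shared with its near-identical copy Hspa1a, Fosb (3.99-fold) and Vwf (5.85-fold), von Willebrand factor of endothelial cells. With the retina-following genes left out, which are themselves calls and were chosen after seeing the data, 2049 genes were called. The split was 3086 higher and 611 lower with library size only, 2381 and 509 on log2(FPKM + 1), and 3915 and 464 scaled to lens fibre genes, where the median of all genes moved by 0.128, 0.117 and 0.177.

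Retinal markers rose with EGCG in 31 of 34 cases, with none lower and a median log2 fold change of 2.78, a 6.88-fold increase (camera with an estimated correlation, adjusted p = 2.09e-06). It was the only list of this comparison that camera called with an estimated correlation. Red blood cell markers rose in 4 of 7 cases, with a median of 1.5 (camera adjusted p = 0.0265, but adjusted p = 0.116 with an estimated correlation). Hbb-bs rose 3.30-fold to 8.60 ± 1.33 CPM, Hba-a1 3.15-fold to 9.28 ± 2.17 CPM, Hba-a2 2.65-fold and Hbb-bt 3.10-fold. Without EGCG replicate 1 the Hbb-bt change was 1.055 on the log2 scale and not called (adjusted p = 0.101), and without aged control replicate 1 that of Hba-a2 was 2.2, against 1.41 with all libraries. In the same libraries the retinal share of CPM without Dkk3 was 0.19% in aged control and 1.28% in EGCG.

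Crystallins fell with EGCG in 13 of 16 cases, with none higher and a median of −0.35 (camera adjusted p = 2.07e-07, but adjusted p = 0.0702 with an estimated correlation), and 13 lower and 1 higher when adjusted over the list alone. The median was −0.22 with library size only, with 12 lower, and −0.17 scaled to lens fibre genes, with 10 lower and 1 higher. The 1 higher in the list alone, named after its values were seen, was Cryga, with 0 to 1 counts per aged control and 0 to 5 per EGCG library. Cryab, a small heat shock protein, fell 1.34-fold from 23710 ± 671 to 17670 ± 211 CPM, Cryba1 1.31-fold, Crygb 1.60-fold and Crygc by a log2 fold change of −0.58. Genes of the lens capsule and basement membrane fell in 20 of 26 cases, with none higher and a median of −0.33 (camera adjusted p = 6.56e-08, but adjusted p = 0.0702 with an estimated correlation), and in 22 when adjusted over the list alone. With library size only 13 were lower with a median of −0.21, and scaled to lens fibre genes 10 with −0.16. Fbln1, fibulin 1, fell 1.53-fold from 231 ± 10.6 to 151 ± 4.85 CPM, Pxdn, peroxidasin, which crosslinks collagen IV, 1.44-fold, Col18a1 1.42-fold, and Col4a1, a chain of collagen IV, 1.26-fold. Genes of epithelial-mesenchymal transition and fibrosis fell in 12 of 27 cases (14 when adjusted over the list alone) and rose in 1, with a median of −0.33 (camera adjusted p = 0.000329, but adjusted p = 0.0702 with an estimated correlation). They had 9 lower, 1 higher and a median of −0.20 with library size only, and 8, 3 and −0.15 scaled to lens fibre genes. Besides Ccn2, Acta2, smooth muscle actin, fell 1.41-fold from 739 ± 22 to 524 ± 15.2 CPM, Loxl2, a collagen-crosslinking oxidase, 1.62-fold, and Itgav, an integrin chain, 1.32-fold. The 1 higher member, named after its values were seen, was Mmp9 (3.79-fold). In the same libraries the ciliary epithelium and zonule list had a median of −0.62, with 15 of 19 lower, and the fibroblast and corneal stroma list one of −0.40, with 7 of 16 lower, which was −0.22 with 4 lower scaled to lens fibre genes.

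Inflammatory signalling genes fell with EGCG in 9 of 25 cases and rose in 1, with a median of −0.37 (camera adjusted p = 0.00652, but adjusted p = 0.0702 with an estimated correlation), which was −0.24 with library size only, with 8 lower, and −0.19 scaled to lens fibre genes, with 7 lower. Serpina3n fell 1.83-fold from 52 ± 4.52 to 28.4 ± 2.16 CPM, Il33, an epithelial alarmin, 1.78-fold, and Tlr2 2.46-fold, while Tnfaip3, an inhibitor of NF-κB signalling, rose 1.84-fold. Ciliary epithelium and zonule genes fell in 15 of 19 cases and rose in 2, with a median of −0.62 (camera adjusted p = 0.00635, but adjusted p = 0.0702 with an estimated correlation). Efemp1 fell 1.68-fold and Ltbp2, a protein of the zonular fibres that hold the lens, 1.53-fold. The 2 that rose, Atp1b2 (3.02-fold) and Crb1 (4.11-fold), are also expressed in the retina.

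**Figure D3:**
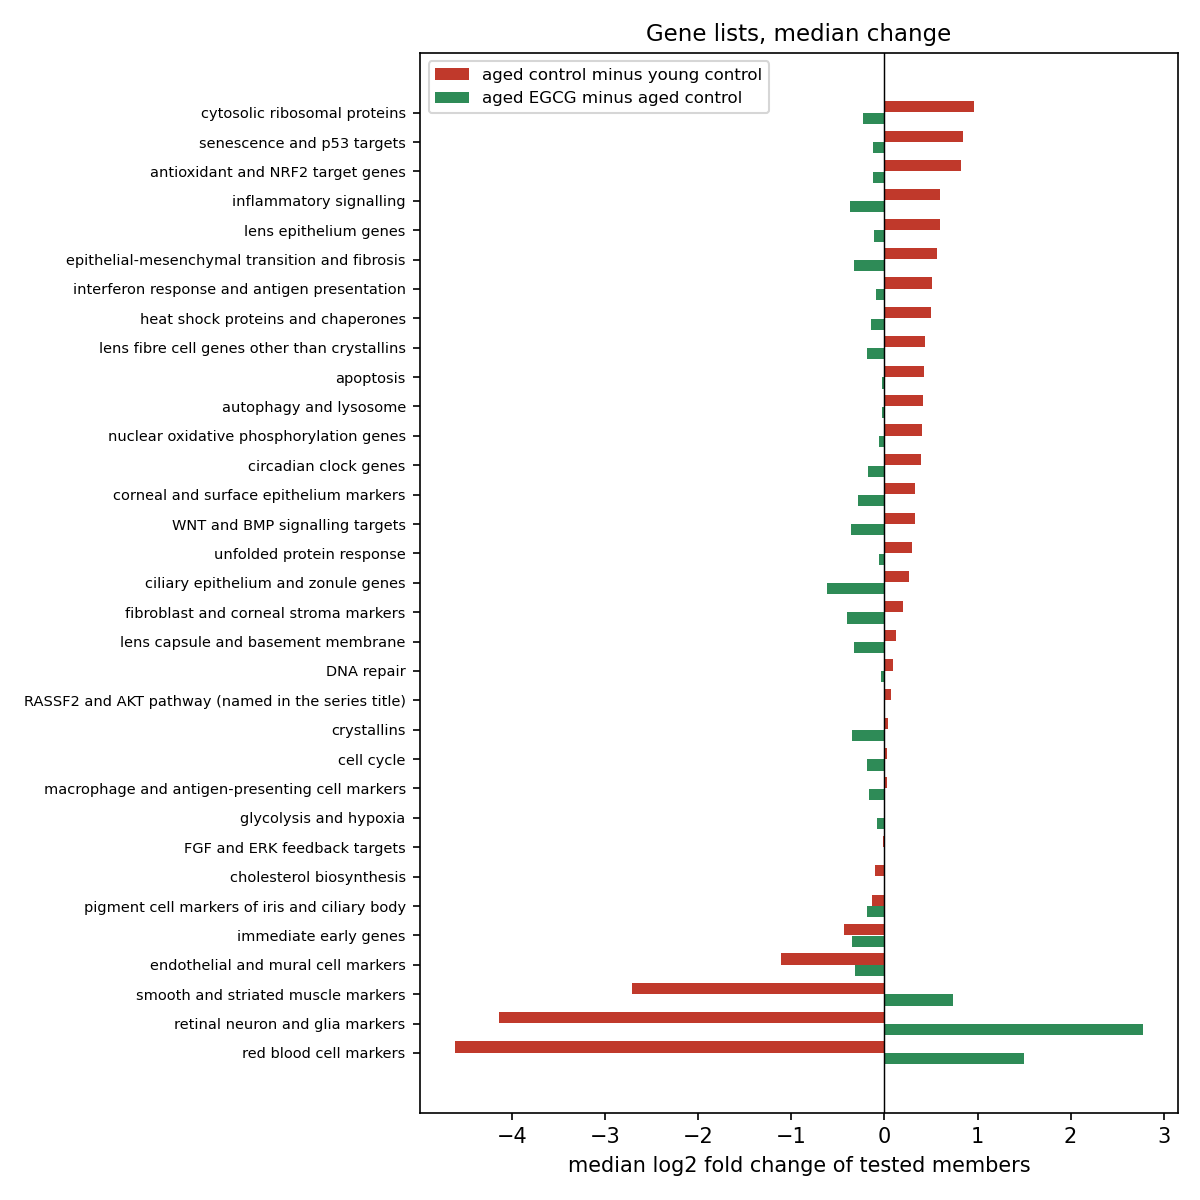
Median log2 fold change of the tested members of each gene list for aged control minus young control and aged EGCG minus aged control, with bars from 0, 3 libraries per group. Retinal markers have medians of −4.14 and 2.78 and red blood cell markers of −4.62 and 1.5, while ribosomal protein genes have 0.96 and −0.23.

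Of the senescence and p53 target list, 16 of 26 genes were not called under EGCG, while 7 were lower (8 when adjusted over the list alone) and 3 higher. The median was −0.12, but 0.04 on log2(FPKM + 1) and 0.05 scaled to lens fibre genes, with no camera call (adjusted p = 0.139). The split turned to 6 higher and 3 lower with library size only and to 7 and 3 scaled to lens fibre genes. Igfbp7 fell 1.33-fold, Igfbp5 1.54-fold and Ccl2, a secreted chemokine, 2.75-fold. Plk2 rose 2.52-fold and is by its changes among the retina-following genes. The other 2 that rose, named after their values were seen, were Lmnb1 (1.53-fold) and Sesn2 (1.65-fold). Of the antioxidant and NRF2 targets, 13 of 38 were lower (14 when adjusted over the list alone) and 2 higher, with a median of −0.12 that was 0.01 with library size only and on log2(FPKM + 1) and 0.06 scaled to lens fibre genes, with 6 higher and 7 lower in the first setting and 6 and 5 in the last (camera adjusted p = 0.00252, but adjusted p = 0.185 with an estimated correlation). Gpx3 fell 1.58-fold from 517 ± 25.9 to 328 ± 13.8 CPM, Sod3, extracellular superoxide dismutase, 1.79-fold, Prdx6 1.34-fold and Gstm1 1.32-fold. The 2 higher members, named after their values were seen, were Srxn1 (1.26-fold) and Gpx4 (1.12-fold). Cytosolic ribosomal protein genes were lower in 69 of 76 cases (72 when adjusted over the list alone), by a median of −0.23 (camera adjusted p = 1.04e-11, but adjusted p = 0.338 with an estimated correlation). Examples were Rpl21 (1.30-fold), Rpl27a (1.29-fold), Rps26 (1.25-fold) and Rpl39 (1.26-fold). With library size only 28 were lower with a median of −0.10, with the length trend removed 39 were lower and 1 higher with −0.11, and scaled to lens fibre genes 9 were lower and 1 higher with −0.05.

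The direction of change under EGCG was set against that with age over the 13711 genes. Genes called in both comparisons moved in opposite directions in 2729 cases and in the same direction in 203. Of the opposite ones, 1726 were lower with age and higher with EGCG, where independent lists of these sizes would share 640, and 1003 were higher with age and lower with EGCG, where they would share 497. Among the former were Gnat1 and Slc16a1, and among the latter Rassf2, Slc5a3, Ccn2, Krt19 and Gpx3. The number of 1003 depended on scaling. All genes called lower with EGCG were 1406 in the main fit. They were only 611 with library size only, 509 on log2(FPKM + 1) and 464 scaled to lens fibre genes. The opposite genes of both kinds together were 2868, 2229 and 3407 in these settings. Of 9482 genes changed with age, 6550 were not called under EGCG, and 7810 still differed from young control in the same direction. The log2 fold changes correlated across genes with Pearson's r −0.759 and a Spearman correlation of −0.567, with a covariance of −0.778. Both comparisons use the aged control libraries, and in 20 simulations with no change in any group r averaged −0.507, the covariance −0.0241 and the number of genes called in opposite directions 0, so the covariance differed from the simulated one by −0.754. The 3 aged control libraries cannot be split with at least 2 in each part, so part of the excess of opposite calls over independent lists may come from shared libraries. Leaving out the retina-following genes, which were picked for opposite changes so that both values shrink by construction, gave an r of −0.504 and 1493 opposite genes.

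**Figure D4:**
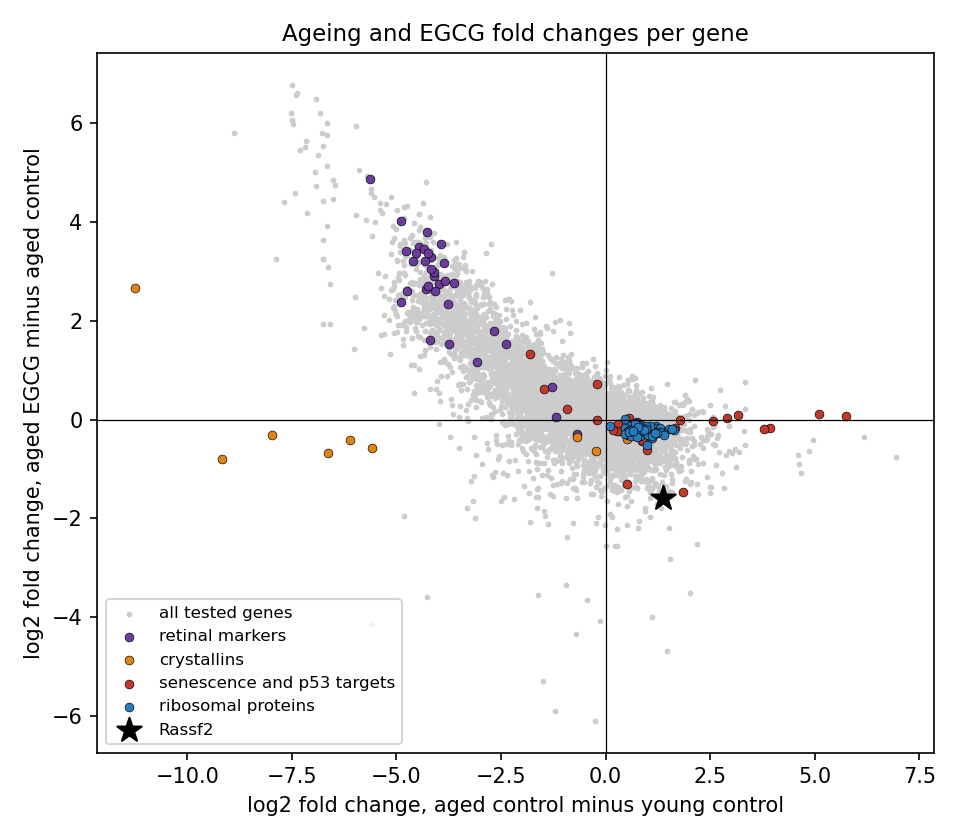
Log2 fold change of aged control minus young control (x axis) against aged EGCG minus aged control (y axis), 1 point per tested gene, 3 libraries per group. Most retinal markers lie at the upper left, Cdkn1a lies at 5.75 with age and 0.08 with EGCG, Crygb at −6.64 and −0.68, and Rassf2 at 1.38 and −1.58.

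Aged EGCG capsule differed from young control in the γ-crystallins Crygb, Crygc and Crygd, in genes of the senescence and p53 target list and in retinal markers. Crygb was 160-fold lower, Crygd 92.3-fold and Crygc 71.7-fold, and Crygf was at 0.145 ± 0.195 CPM against 153.5 ± 0.728. Ccng1 was 7.68-fold, Cdkn1a 56.9-fold and Aldh3a1 3.78-fold higher, Phlda3 9.62-fold and Cdkn2b 12.1-fold. In all 8725 genes were called, 4424 higher and 4301 lower, and 671 and 1986 at a change of at least 2-fold. The libraries did not overlap in 68.3% of genes, where chance gives 10%. The senescence and p53 target list was higher in 18 of 26 cases and lower in 3, with a median of 0.48 (camera adjusted p = 0.00587 with an estimated correlation), the 3 being Lmnb1, Plk2 and Sirt1, named after their values were seen, but in 14 and 5 with a median of 0.28 with library size only and in 11 and 7 with 0.17 scaled to lens fibre genes. Crystallins were higher in 7 of 16 cases and lower in 8, with a median of −0.39 and a mean of −2.90 (camera adjusted p = 0.00587 with an estimated correlation), and 4 higher and 11 lower with a median of −0.58 with library size only and 3 and 11 with −0.70 scaled to lens fibre genes. Retinal markers were lower in 33 of 34 cases, with a median of −1.11 (camera adjusted p = 0.000478 with an estimated correlation), Dkk3 being the exception. Among them were Rp1 (5.69-fold), Abca4 (3.80-fold) and Pde6a (3.13-fold), long genes of 12614, 9488 and 8181 bp. Across all genes the difference from young control went with gene length (Spearman correlation −0.36), with a median of −0.6 in the longest 10%. Akt1 (log2 fold change 0.59) and Akt2 (0.66) were higher in EGCG than young control libraries. The split of all calls was 3098 higher and 5575 lower with library size only, 3113 and 4840 on log2(FPKM + 1), and 2466 and 6380 scaled to lens fibre genes, where the median of all genes moved by −0.194, −0.182 and −0.306.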

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

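The settings without the retina-following genes, scaled to lens fibre genes and with the gene-length trend removed were chosen after seeing the data, and the others before. Counts of changed genes stayed within 1.5 times the reported ones under the other scalings, tools and filters, and when any 1 library was left out (8960 to 9666 for aged against young control, 2803 to 3247 for EGCG against aged control, 8009 to 8916 for EGCG against young control). With a 2-fold threshold added, which only removes calls, they were 3642, 1130 and 2657. Without the retina-following genes, which are themselves calls, EGCG against aged control gave 2049 genes, 984 higher and 1065 lower. The correlation of the age and EGCG changes was −0.504 and 1493 genes moved in opposite directions in that setting, which removes genes picked for opposite changes. The correlation was −0.615 with DESeq2, which was also run without the filter on low counts, and −0.593 in edgeR without that filter. With limma-voom, which kept the filter, it was −0.753. The cause of these differences was not tested. With 1 library left out the correlation was −0.771 to −0.705, and 2342 to 2722 genes moved in opposite directions. Summed over the 3 comparisons, 41 calls of lists with the preset correlation became 9 with an estimated correlation and 83 with fry, which does not compare a list with other genes.

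Rassf2 kept its direction and its call in each setting that gave it a value and without any 1 library (1.168 to 1.576 with age and −1.778 to −1.36 with EGCG). The filter on at least 5 CPM in at least 3 libraries gave it no value, and on log2(FPKM + 1) its changes were 0.379 and −0.48. Of the other named-gene values under alternatives, 3804 were either called in the same direction in both fits or called in neither. With the sign kept, 11 lost their call and 5 gained one, and 0 reversed with a call in either fit. Signs were not compared for values called in neither fit. Counting error alone gives Rassf2 a coefficient of variation of 18.3% in young control, 12.1% in aged control and 21.2% in EGCG libraries, next to 7.5%, 27.7% and 22.7% observed, so depth is not the only limit in aged control. Depth also limits genes near the floor such as Cryga and Crygf in the aged groups.

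With the replicate number as a block, 9451, 3338 and 8694 genes were called in the 3 comparisons, of which 9401, 3244 and 8625 were also called without it. Deviations of libraries with the same number correlated across genes between −0.034 and 0.067, with 0 of 9 pairs over 0.1, so the libraries were not treated as paired. Between aged control and EGCG libraries, the same-number correlations were 0.047 to 0.067 and the others −0.066 to 0.008, and each of the 6 libraries correlated best with its own number in the other group, a hint from the data and not from the design. Against young control, 0 of 6 did so in either comparison.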

Other observations

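Members of other gene lists changed with age, in lists with no camera call or a camera call lost with an estimated correlation. Autophagy and lysosome genes were higher in aged than young control in 25 of 37 cases and lower in 5, with a median log2 fold change of 0.41 (camera adjusted p = 0.00081, but adjusted p = 0.066 with an estimated correlation), which was 0.08 with library size only, with 16 higher and 11 lower, and turned to −0.08 scaled to lens fibre genes, with 12 and 15. Sqstm1, the autophagy receptor p62, rose 3.01-fold from 195 ± 6.09 to 586 ± 17.6 CPM (SD, n = 3 each), Bnip3l, a mitophagy receptor, 2.14-fold and Ctsd, the lysosomal protease cathepsin D, 1.79-fold. The 5 lower members, named after their values were seen, were Map1lc3a, Atg9a, Atg16l1, Gabarapl1 and Rubcn. Nuclear genes of oxidative phosphorylation were higher in 42 of 54 cases and lower in 2, Ndufa4 and Ndufs1, named after their values were seen. Their median was 0.40 (camera adjusted p = 0.00148, but adjusted p = 0.521 with an estimated correlation), which was 0.08 with library size only, with 22 higher and 15 lower, and turned to −0.02 with the length trend removed (16 and 19) and −0.08 scaled to lens fibre genes (8 and 24). Ndufb10 rose 1.84-fold, Cox6a1 1.97-fold and Sdhb 2.04-fold. Smooth and striated muscle markers were lower in 7 of 9 cases and higher in 1, with a median of −2.71 and no camera call (adjusted p = 0.307), but on log2(FPKM + 1), which compresses low levels, 2 were lower with a median of −0.58. Myh11, smooth muscle myosin, fell 6.89-fold and Synpo2 3.41-fold, and the 1 higher member, named after its values were seen, was Mylpf.

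Of further lists, camera called these lower in EGCG than in aged control libraries with the preset correlation and not with an estimated one, and fry called them too. Immediate early genes fell in 11 of 24 cases and rose in 2, with a median of −0.35 (camera adjusted p = 0.00191, but adjusted p = 0.0715 with an estimated correlation), and 10 lower, 3 higher and −0.22 with library size only and 9, 5 and −0.18 scaled to lens fibre genes. Dusp1, a phosphatase of MAP kinases, fell 1.79-fold from 98.6 ± 5.63 to 55 ± 0.515 CPM, Ccn1 1.92-fold, Fos 1.56-fold and Fosb 3.99-fold. The 2 that rose, named after their values were seen, were Nr4a1 (1.60-fold) and Klf6 (1.17-fold). Fibroblast and corneal stroma markers fell in 7 of 16 cases with none higher, with a median of −0.40 (camera adjusted p = 0.00252, but adjusted p = 0.0702 with an estimated correlation), and 4 lower with −0.27 with library size only and 4 with −0.22 scaled to lens fibre genes. Fmod, fibromodulin, fell 1.74-fold, Igfbp4 1.65-fold, Col6a2 1.39-fold and Col6a3 1.32-fold. Circadian clock genes fell in 9 of 19 cases and rose in 1, with a median of −0.18 (camera adjusted p = 0.00768, but adjusted p = 0.0702 with an estimated correlation), but 5 lower, 3 higher and −0.06 with library size only and 5, 4 and −0.01 scaled to lens fibre genes. Bhlhe40 fell 1.73-fold, Per1 1.53-fold and Bhlhe41 1.33-fold, and the 1 that rose, named after its values were seen, was Arntl (1.24-fold). Heat shock proteins and chaperones fell in 11 of 22 cases (14 when adjusted over the list alone) and rose in 1, with a median of −0.14 that was −0.01 with library size only, with 4 lower and 2 higher, and 0.04 scaled to lens fibre genes, with 3 and 2 (camera adjusted p = 0.00592, but adjusted p = 0.0702 with an estimated correlation). Hspb1 fell 1.40-fold and Hsph1 1.44-fold, while Hsp90aa1 rose 1.20-fold.

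All tests below were chosen after the results were seen. The 1016 genes at least 2-fold higher in EGCG than aged control were, in 1011 cases, lower in aged than young control, a direction held by 33.8% of all genes tested. More retinal RNA in the EGCG libraries is a candidate explanation, since 31 of 34 retinal markers were called higher and the sum of those other than Dkk3 went from 0.19% to 1.28% of CPM. A part of a young library mixed into the EGCG libraries is argued against by Crygb, Crygc and Crygd, whose sum recovered a share of −0.0047 of its loss with age, against 0.147 to 0.751 for the 24 abundant retinal markers that are on no other list (Trpm1 with 0.031 and Dkk3 with 0.097 are on another and were left out). Whether this is retinal RNA of 1 composition stays open, since the highest share was 5.1 times the lowest (Guca1a over Rp1) but the shares went with gene length (Spearman correlation −0.55 across genes), and a length bias could give such a spread. Whether the rest reflects dissection, RNA quality or an effect of age or EGCG on the retina stays open, and no label separates these.

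The rise of 75 of 76 ribosomal protein genes with age went with a fall of long genes. Other genes matched on length and on level in aged control numbered 324, of which 291 were called higher. Their median was 0.84 next to the ribosomal 0.96. Matching on the aged level favours genes that are higher in aged control, so these values do not isolate the effect of length. With the trend over gene length removed, 64 ribosomal protein genes were still called higher, with a median of 0.50. The trend was fitted over all genes and the matched genes were not examined after its removal, so the trend alone is not excluded. On the lens fibre scale, which moved the median of all genes by −0.483, 65 were called higher. The rise was thus larger than that of the lens fibre genes, which does not decide whether another scale would remove it. With the length trend removed and the lens fibre scale used together, 45 were called higher and 13 lower, with a median of 0.20. Most of the size of the change may therefore go with these technical choices. Differences in RNA integrity between young and aged tissue, and an effect of age, stay open and were not tested.

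The rise of Rassf2 with age and its fall with EGCG may come from a change in cell types rather than in lens cells. Endothelial RNA is argued against by its markers, whose median was −1.11 with age (upper quartile −0.11), below the Rassf2 change of 1.38. Macrophage RNA is argued against by a median of 0.03 with age (upper quartile 0.34), with −0.17 under EGCG. In the main fit, ciliary epithelium markers went the same way as Rassf2 in both comparisons, but by less. Their median was 0.26 with age (upper quartile 0.76) and −0.62 with EGCG (quartiles −0.71 and −0.5). The median with age turned to −0.07 with library size only, −0.05 on log2(FPKM + 1) and −0.23 scaled to lens fibre genes. These sizes argue against ciliary RNA as the whole account and leave it open as a part. Leaving out the retina-following genes moved the other genes by a median of only −0.095 with age and 0.027 with EGCG. Rassf2 then changed by 1.285 and −1.55 and kept both calls, which this step could hardly have ended. It shows that these genes weigh little on the scaling and does not otherwise test dilution by retinal RNA. The endothelial gene Vwf also fell with EGCG (−2.55), the endothelial median was −0.32 there, and other cell types, a rare cell population and an effect of age or EGCG in lens cells stay open.

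Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. In each comparison 1 of the 10, the real one, gave as many genes (9482, 3300 and 8725), and the highest of the others gave 0. Of 100 splits of the 9 libraries, 2 gave as many genes moving in opposite directions as the real one with 2729. The other kept the 3 groups intact with another group as the shared one and gave 7810, and splits that broke the groups gave at most 658. Splits that break the groups mix libraries that differ widely, which leaves few calls, so the count shows that the groups differ and does not test whether the opposition is beyond chance. The correlation of the changes (−0.759) was as low in 48 of the 100 splits, the lowest of the others being −0.963. For the same reason these splits are no measure of a correlation without change, for which the simulated unchanged groups gave −0.526 to −0.478.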
